A study of Mus musculus with 12 samples.

How the data were processed

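Gene expression was measured in whole hearts of postnatal day 8 mice of the C57bl/6 X 129 hybrid background. Per the labels, total RNA was amplified with an amino-allyl nucleotide, coupled to Cy5, and hybridised as 1 sample to each of 12 oligonucleotide arrays. The arrays came from 4 biological samples, 2 of a Salvador conditional mutant (Salv CKO) and 2 of controls, each hybridised to 3 technical arrays. The source label names embryonic heart, whereas the stage label and the protocol give postnatal day 8, which was used here. Whether a sample was a single heart or a pool, which Cre driver was used and which part of the gene was deleted are not given in the sources used here.

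The deposited values are intensities, that is, the brightness of each probe on a linear scale. The authors' scanner, background method and normalization are not given in the sources used here. The deposited intensities were whole numbers from -10 to 65474 for 26423 probes, with no missing values, and the values below 0 show that a background had been subtracted. Array medians ran from 58 to 88 and 75th percentiles from 348 to 542, so the deposited values were not on a common scale between arrays. The number of biological samples, 2 per group, and not a read depth, limits the precision of the group comparison. At most 5 values on an array exceeded 65000, near the ceiling of the scanner.

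The test design was fixed before the data were examined and left out normalization between arrays unless the array distributions differed. They differed, and the 12 arrays were therefore quantile normalized with limma, a method the design did not name. Values below 0 were set to the lowest positive value (0.0833), and log2(value + 1) was taken. A difference on this scale understates the change of dim probes. The 3 technical arrays of a sample were averaged on the log2 scale and counted as 1 replicate.

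Salv CKO was compared with control by limma (lmFit and eBayes, version 3.58.1, R 4.3.3), 2 samples against 2, with 2 residual and 2.60 prior degrees of freedom. Two-sided p-values were adjusted over all 26423 probes by the Benjamini-Hochberg method, with a threshold of 0.05. The labels call the samples biological replicates and say no more about their origin, so the limma p-values measure the spread between these samples.

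Probes were named from the platform annotation. Of the probes, 20377 had 1 gene symbol, 0 had several and 6046 had none. Symbols were updated through the RefSeq table of GRCm38.p6, where 18213 probes matched by symbol, 2126 by a unique synonym and 38 not at all, leaving 17742 distinct genes. No genome position is printed, because the build behind the probes is not given in the sources used here. A gene with several probes is given by the probe with the highest mean over the 12 arrays.

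The named genes followed a rule fixed before the data were examined. It took Sav1, then up to 10 higher and 10 lower genes with the largest change among those that passed the threshold without overlap between the groups. Where fewer passed, the remaining places went to the genes with the smallest unadjusted p and no overlap. It also took up to 4 members with the smallest p in each of 40 fixed gene lists, and the measured Hippo core genes and targets. Lists of pathways, cell types and other tissues were tested with camera (limma) at a preset correlation between genes of 0.01, and with an estimated correlation. Camera p-values at the preset correlation rest on the spread over genes and do not measure that between samples. Adjustment ran over the 39 lists with at least 3 measured genes.

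The procedure was tested on simulated data for the Salv CKO against control comparison, with 26423 probes drawn from the fitted means and spreads in 5 runs and independent noise. Of probes changed by 1 on the log2 scale, 0 of 335 were called. Of those changed by 2, 69.3% were called, and of those changed by 4, 98.8%. Of unchanged probes, 0.0282% were called. A 28-gene list shifted by 0.5 was called in 5 of 5 runs at the preset correlation and in 0 of 5 with an estimated correlation. Of 190 unchanged lists, 1 was called at the preset correlation.

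Alternatives fixed in advance covered the use of all 12 arrays, a replicate block, the median of technical arrays, median centring, filters on dim probes, the variance model, a pseudocount of 16, each sample left out in turn, the estimated correlation and the mean over probes. Alternatives chosen after seeing the data were no normalization between arrays, a pseudocount of 50, a crossed pairing, a pseudocount of 16 together with the median of technical arrays, and that median for counts of genes in which 1 sample stood apart. Figures were drawn with matplotlib 3.10.9.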

Results

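Expression was profiled in 12 one-colour arrays of whole hearts at postnatal day 8. They comprised 2 samples labelled Salv CKO and 2 labelled Control, with 3 technical arrays each. Salvador (Sav1) is the scaffold protein that brings together the kinases of the Hippo pathway, which restrains the transcriptional co-activators Yap1 and Wwtr1 (Taz). The comparison asked which genes depend on this pathway in the neonatal heart. Sav1 itself did not follow the labels, so each sample is called here by its label only.

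Sav1, the targeted gene, was measured by 1 probe and did not separate the groups. Its log2 intensity was 8.06 in the sample labelled Salv CKO 1 and 8.52 in Salv CKO 2, against 8.75 in Control 1 and 8.08 in Control 2. The deposited intensities averaged 240, 433, 439 and 252 over the 3 arrays of these samples, in that order. The sample labelled Salv CKO 2 thus lay above the sample labelled Control 2. The difference between the groups was -0.12 ± 0.34 (SE, limma, adjusted p = 0.998). It was 0.11 without Salv CKO 1 and 0.21 without Control 1, so its sign rested on single samples. The deleted part of the gene is not given in the sources used here, and a probe outside it would check nothing.

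**Figure D1:**
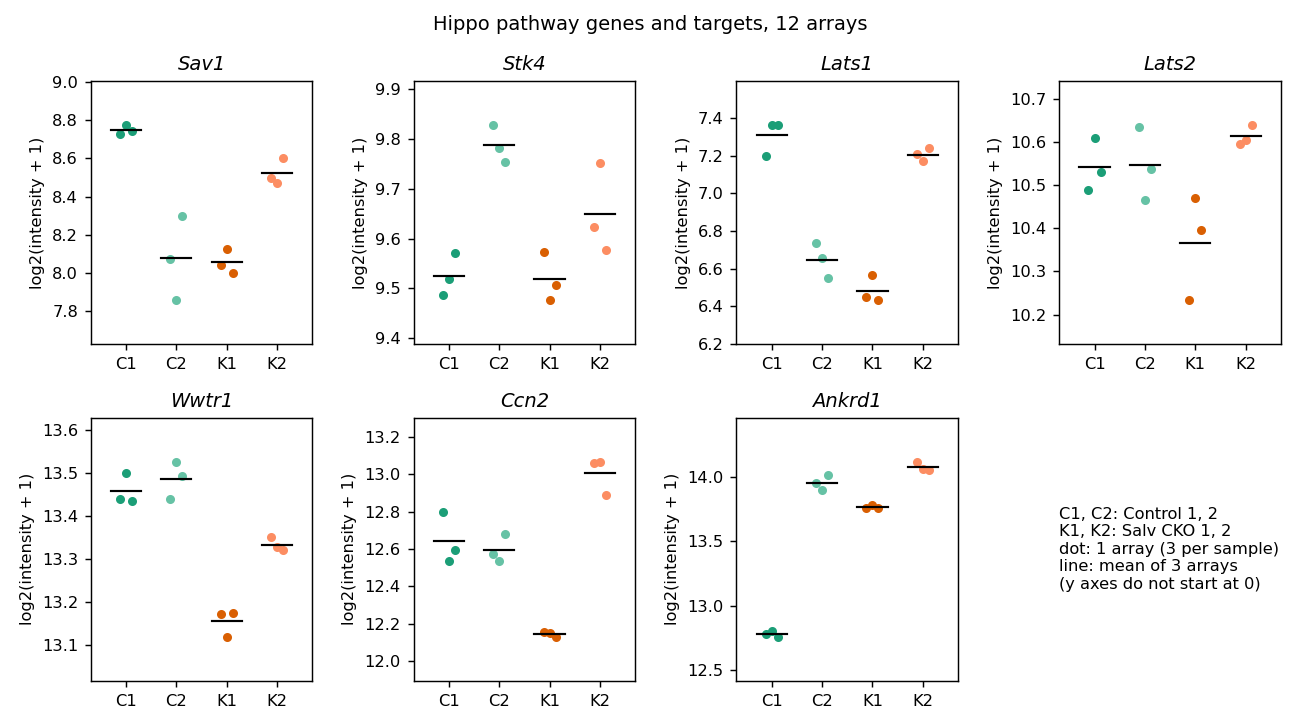
Normalized log2(intensity + 1) of 7 Hippo pathway genes and targets in the 4 samples, with a dot for each of the 3 technical arrays and a line at their mean. For Sav1 the samples labelled Salv CKO 1 (8.06) and Control 2 (8.08) lie below those labelled Salv CKO 2 (8.52) and Control 1 (8.75).

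Of the other Hippo core genes and targets, 6 were measured, and none passed the threshold (limma, smallest adjusted p = 0.998). Ankrd1, a cardiac ankyrin repeat gene and a target of Yap1, differed by 0.55 ± 0.45 (SE). Its level was 12.78 in Control 1 and 13.95 in Control 2, against 13.76 and 14.07 in the samples labelled Salv CKO 1 and 2. Without Control 1 its difference was -0.035. Ccn2, the connective tissue growth factor gene, differed by -0.042 ± 0.35 and had both its lowest level, 12.15, and its highest, 13.01, within the Salv CKO samples. Wwtr1 differed by -0.23 ± 0.21 (-0.14 without Salv CKO 1), Lats1 by -0.13 ± 0.38, Lats2 by -0.055 ± 0.22 and the kinase gene Stk4 by -0.072 ± 0.23. The 2 probes of Lats1 disagreed in direction (-0.13 and 0.64), and the other probe of Lats2, a dimmer one at levels from 2.91 to 5.51, differed by -0.62. Stk3, Yap1 and Ccn1 had no named probe in the annotation used here.

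In the whole-array comparison, 0 of 26423 probes passed an adjusted p of 0.05 in limma (smallest adjusted p = 0.998). At an unadjusted p under 0.05 there were 1048 probes, 514 higher and 534 lower in the samples labelled Salv CKO, where 1321 would be expected from uniform p-values. This count of 1048 ran from 638 without Salv CKO 1 to 2824 without Control 2. The 2 groups did not overlap for 8085 probes, or 30.6%, against 33.3% by chance. No gene named in the next paragraph passed the threshold, and their differences are given as values.

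Among the 10 higher genes with the smallest p, Slx1b, a structure-specific endonuclease subunit, differed by 3.38 ± 0.25 (SE), and by 2.47 at a pseudocount of 16. Slx1b intensities were 139 and 153 in the samples labelled Salv CKO against 15.7 and 11.2 in the controls. Trim12a, a tripartite motif gene, had intensities of 146 and 186 against 4.08 and 0.861, which are near background, so the size of its difference depends on the pseudocount (5.77 at 1 and 3.29 at 16). When each array was centred on its median, Trim12a passed with an adjusted p of 0.0015 in limma and Slx1b with 0.0163. Tecrl, a reductase-like gene of heart muscle, differed by 1.44 ± 0.21, with levels of 9.09 and 8.95 against 7.65 and 7.50. Csrnp3 and Zfp994 were dim in the controls, and their differences of 2.37 and 2.66 became 1.44 and 1.25 at a pseudocount of 16. The serotonin receptor gene Htr1b, also dim, differed by 1.44, and by 0.83 at that pseudocount. Wnt10b, Olfr220 and Olfr1500 stood at intensities of at most 5.83, close to background. Ubn2 differed by 2.37, but this rested on 1 array of each control at an intensity of 2 and 1, and with the median of technical arrays the difference was 0.062.

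Among the 10 lower genes, Lrrc3b differed by -2.35 ± 0.23 (SE) and Stbd1, which binds glycogen, by -2.11 ± 0.24. Stbd1 levels were 8.29 and 8.14 in the samples labelled Salv CKO against 10.50 and 10.15 in the controls. Plekhh1 differed by -1.72, the secretoglobin gene Scgb1c1 by -1.52 and Ubxn10 by -1.51. Tent5d, Lrrc37a and the myelin protein gene Pmp2 had intensities of at most 7.08. Tom1l2 differed by -2.70, which rested on 1 array of each Salv CKO sample at an intensity of 32 and 3. With the median of technical arrays its difference was -0.21, and its other probe differed by 0.26. The difference of -2.04 in the cystatin gene Cst11 likewise rested on 1 array of each Salv CKO sample, at an intensity of 5 and 6, and was -0.48 with the median of technical arrays.

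**Figure D2:**
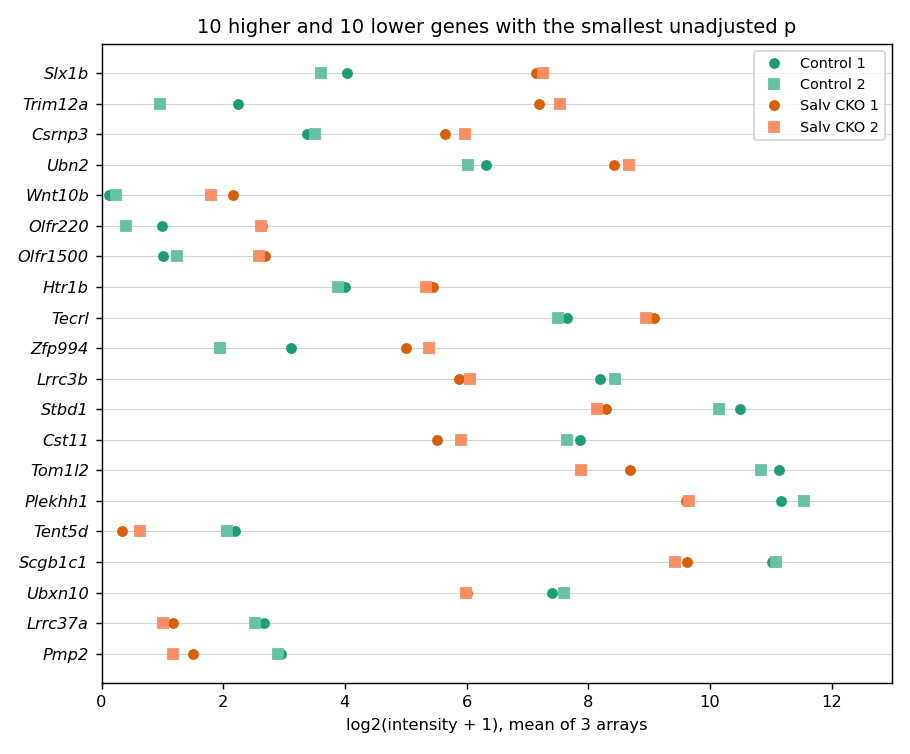
Mean log2(intensity + 1) over 3 technical arrays of the 10 higher and 10 lower genes with the smallest unadjusted p and no overlap between the groups, with 1 symbol for each of the 4 samples. Slx1b lies at 7.13 and 7.26 in the samples labelled Salv CKO against 4.04 and 3.60 in the controls, and none of the 20 genes passed the adjusted threshold.

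Genes of the G2 and M phases of the cell cycle were higher as a group in the samples labelled Salv CKO. All 28 measured genes had a positive difference, with a median of 0.48, and 19 did not overlap between the groups. Camera called the list at the preset correlation (adjusted p = 9.17e-13). With an estimated correlation between genes (-0.029 for this list) it did not pass (adjusted p = 0.516). That setting called a simulated list shifted by 0.5 in 0 of 5 runs. Not passing there therefore decides nothing for this list. The simulated noise was independent between genes, so the simulation does not cover lists of correlated genes, such as the intercalated disc and adipocyte lists below. At an unadjusted p under 0.05 there were 11 members (2 with the replicate block), and 0 passed over all genes or adjusted over the list alone (smallest 0.126). Among them, the cyclin gene Ccnb2 differed by 1.12 ± 0.34 (SE) and Ube2c, which targets mitotic cyclins for degradation, by 1.02 ± 0.34. The mitotic kinase genes Plk1, Aurkb, Bub1 and Ttk differed by 0.93, 0.72, 0.63 and 0.67. Hmmr differed by 0.69, and Cdca8, Cdca3, Birc5 and Anln by 1.15, 0.61, 0.60 and 0.54. The other probe of Bub1 differed by -0.034, that of Ttk by 0.43, and the other 2 of Birc5 by 0.90 and 0.25. Without Control 1, Ccnb2 differed by 0.74 and Cdca8 by 0.66, and without Control 2, Plk1 differed by 0.62. The list was called without each sample in turn, with medians from 0.51 to 0.56. Positive differences then numbered 22 to 27 of 28. Because Sav1 did not follow the labels, the direction is that of the labels only.

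**Figure D3:**
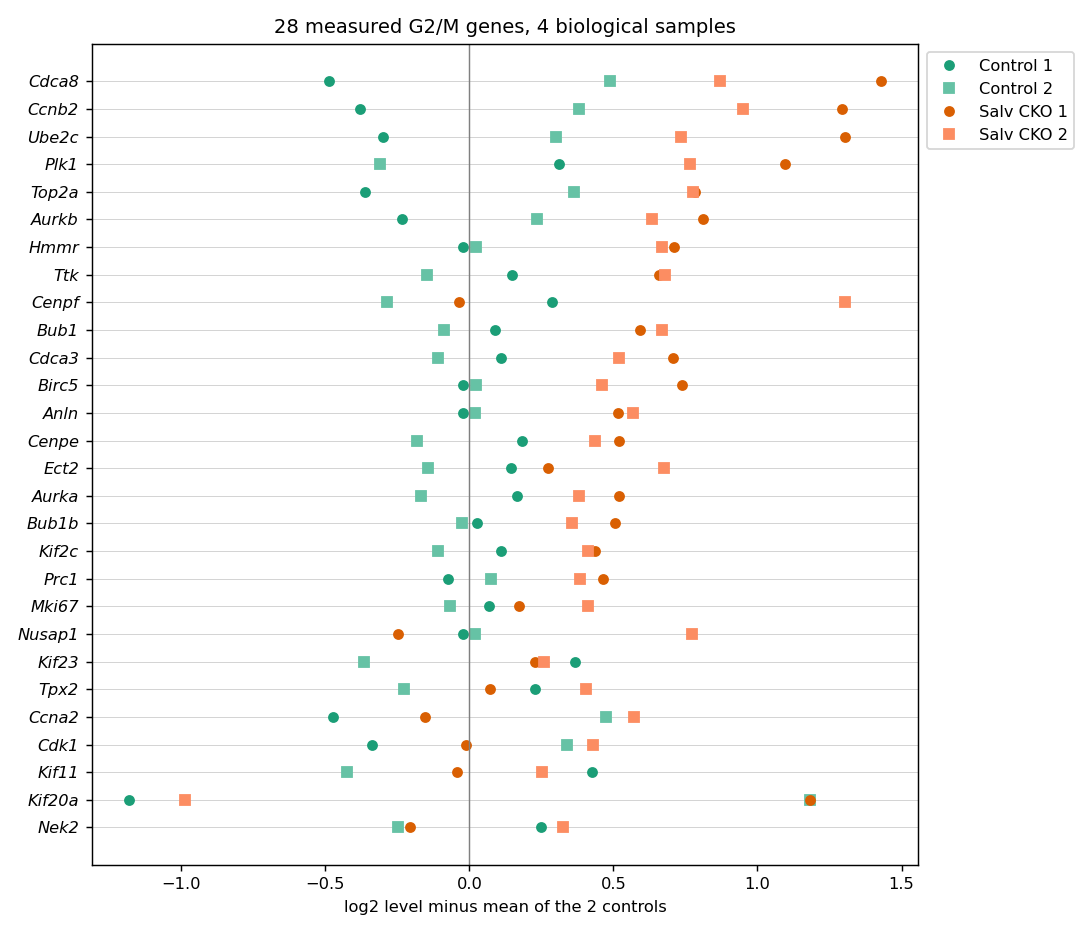
Level of 28 genes of the G2 and M phases in each of 4 samples, as log2(intensity + 1) minus the mean of the 2 controls. The 2 Salv CKO samples lie above both controls for 19 genes, and the median difference between the groups is 0.48.

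Genes of the G1 and S phases gave no such call. Of 24 measured, 14 had a positive difference, the median was 0.020, and camera gave an adjusted p of 0.592. Rrm1, the ribonucleotide reductase subunit, differed by 0.57 and Gins2 by 0.33. Among the inhibitors of the cycle, 5 of 12 were positive (camera adjusted p = 0.643), with Cdkn2b at 0.32 and Cdkn1a at 0.28.

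Genes of the intercalated disc and costamere, which join and anchor heart muscle cells, were called higher by camera (adjusted p = 0.0254). With the estimated correlation of 0.24 between these genes, above the preset 0.01, the list was not called (camera adjusted p = 0.92). Of 25 measured, 19 had a positive difference with a median of 0.12, and 0 passed over all genes or adjusted over the list alone. The desmosome genes Pkp2 and Dsp differed by 0.55 and 0.52, and the actin regulator gene Enah by 0.51. Without Control 1 these were 0.35, 0.32 and 0.30. The call was lost without Control 1 (median 0.013, adjusted p = 0.712) and without Salv CKO 2 (median 0.037, adjusted p = 0.277). It was also lost when arrays were centred on their medians or not normalized, and without moderation. The split by sample number, which ignores the groups, called the list too, lower in the samples numbered 1 (median -0.16, 3 of 25 positive, camera adjusted p = 0.0064). That split called 5 lists, against 3 as labelled, and 0 each with an estimated correlation.

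Adipocyte genes were called lower by camera (adjusted p = 0.0215), and not with an estimated correlation (adjusted p = 0.92). Of 13 measured, 11 had a negative difference, with a median of -0.47, and 0 passed adjusted over the list alone. Ucp1, the uncoupling protein of brown fat, stood at 9.75 in the sample labelled Salv CKO 2, against 11.95 in Salv CKO 1, 12.71 in Control 1 and 11.74 in Control 2. Adipoq (7.13), Plin1 (7.31) and Cidec (5.82) were also lowest in Salv CKO 2. Cfd, the adipsin gene, differed by -1.80 ± 0.48 (SE), and by -1.16 without Salv CKO 2. The call was lost without Salv CKO 2 (median -0.20, adjusted p = 0.407) and without Control 2 (median -0.37, adjusted p = 0.415).

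Genes of the fetal heart program did not pass as a list (camera adjusted p = 0.257, median -0.15, 6 of 16 positive). The median ran from -0.24 to -0.073 with 1 sample left out. Adjusted over the list alone, 2 members passed, and 0 over all genes. Tagln, a smooth muscle and fetal heart actin-binding protein, had levels of 3.72 and 3.18 against 5.68 and 5.22 (limma, list-alone adjusted p = 0.029). It was dim, with deposited intensities of 35, 5 and 12 on the arrays of Salv CKO 1, 8 to 9 in Salv CKO 2 and 28 to 47 in the controls. The arrays of Salv CKO 1 alone spanned 2.37 to 5.05, and the difference in Tagln was -1.13 at a pseudocount of 16. Skeletal actin, Acta1, differed by -1.27 ± 0.27 (limma, list-alone adjusted p = 0.0487, and 0.0618 with the median of technical arrays). Without any 1 of the 4 samples neither Tagln nor Acta1 passed over this list (limma, list-alone adjusted p from 0.0623 to 0.356). Over all other settings Tagln did not pass in 6 of 17 and Acta1 in 8 of 18, among them no moderation for both and the replicate block for Acta1 (0.136). Cacna1h differed by -0.76 and the slow troponin gene Tnni1 by 0.65. In the smooth muscle and pericyte list, Tagln passed adjusted over the list alone (limma, adjusted p = 0.0217). It did not pass in 6 of 17 other settings: without Control 1 (0.102) or Salv CKO 2 (0.0748), with the sample as a random block (0.0858), no moderation (0.18), a pseudocount of 50 (0.111) or the crossed pairing (0.0553). Cnn1, at intensities from -2 to 6, and Lmod1, at 10 to 35, were too dim for their differences to be read. That list had 8 of 12 negative differences, a median of -0.14 and a camera adjusted p of 0.0629. It was called in 4 other settings with all samples, and its median ran from -0.20 to -0.092 with 1 sample left out.

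The pathway lists nearest to the question were not called. Hippo components had 7 of 29 positive differences (median -0.072, camera adjusted p = 0.751). Tead4, at intensities of at most 29.9, differed by 0.53, by 0.32 with a pseudocount of 16 and by 0.30 without Control 2. Mob1a stood at 5.58 in Control 1 and at 7.24 in Control 2, against 7.48 and 7.13 in the samples labelled Salv CKO, so the groups overlapped. Yap1 and Wwtr1 target genes had 10 of 29 positive (median -0.073, camera adjusted p = 0.751). Birc5, which is also in the G2 and M list, and Amotl2 had the smallest p there, with differences of 0.60 each. Without Control 1, Amotl2 differed by 0.35. Targets of Wnt and beta-catenin had 13 of 21 positive (median 0.062, camera adjusted p = 0.592). Lgr6, at 0.83, and Wif1, at -0.93, had the smallest p there. Insulin-like growth factor signalling had 7 of 20 positive (adjusted p = 0.592).

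Among metabolic lists, cholesterol synthesis had 11 of 15 positive (median 0.21, camera adjusted p = 0.0738) and was called in 6 other settings with all samples. Its median ran from 0.063 to 0.29 with 1 sample left out. Fdps differed by 0.85 and Srebf2 by 0.48, and without Control 1 by 0.35 and 0.29. Oxidative phosphorylation had 16 of 27 positive (adjusted p = 0.695) and glycolysis 8 of 18 (adjusted p = 0.751). Fatty acid oxidation had 9 of 24 positive (adjusted p = 0.695), with Angptl4 at -0.98, and at -0.51 without Control 2.

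Heart muscle and channel lists were not called. Sarcomere genes had 5 of 12 positive (camera adjusted p = 0.772), calcium and ion channel genes 9 of 19 (0.751), atrial and conduction genes 7 of 15 (0.795) and ventricular genes 4 of 9 (0.714). Kcnd2, a potassium channel gene, differed by -1.15, and Scn4b was dim, with intensities of 7.36 and 5.06 in the controls. Ribosomal protein genes had 4 of 12 positive (0.772).

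Stress and immune lists were not called. Camera adjusted p was 0.592 for antioxidant and heat shock genes, 0.695 for the unfolded protein and hypoxia responses, 0.751 for immediate early genes, 0.829 for apoptosis and 0.907 for the circadian clock. The clock repressor gene Nr1d1 differed by -0.76. Interferon response genes had 15 of 21 positive (adjusted p = 0.257) and inflammation genes 6 of 20 (adjusted p = 0.555). For cell cycle inhibitors, sarcomere, channels, ribosomal proteins, macrophage and lung, thymus and liver lists the median was negative while camera pointed up. For fibroblast and circadian genes the median was positive while camera pointed down.

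No list of markers of other cell types was called apart from adipocytes, but single samples stood out. Erythroid genes had a median of 0.42 (camera adjusted p = 0.257), with Alas2 at 12.32 in Control 2 and from 13.08 to 13.66 in the others. The list of lung, thymus and liver markers was not called (adjusted p = 0.768). Scgb1a1, an airway secretory protein, stood at 8.14 in Salv CKO 1 and 11.19 in Control 2, against 4.07 in Salv CKO 2 and 3.68 in Control 1. Camera adjusted p was 0.751 for fibroblast, endothelial and lymphocyte genes, 0.363 for epicardial, 0.955 for macrophage, 0.274 for neutrophil, 0.695 for skeletal muscle and 0.592 for neural genes. Of the Y-linked and Xist list, 2 genes were measured and no test was made.

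**Figure D4:**
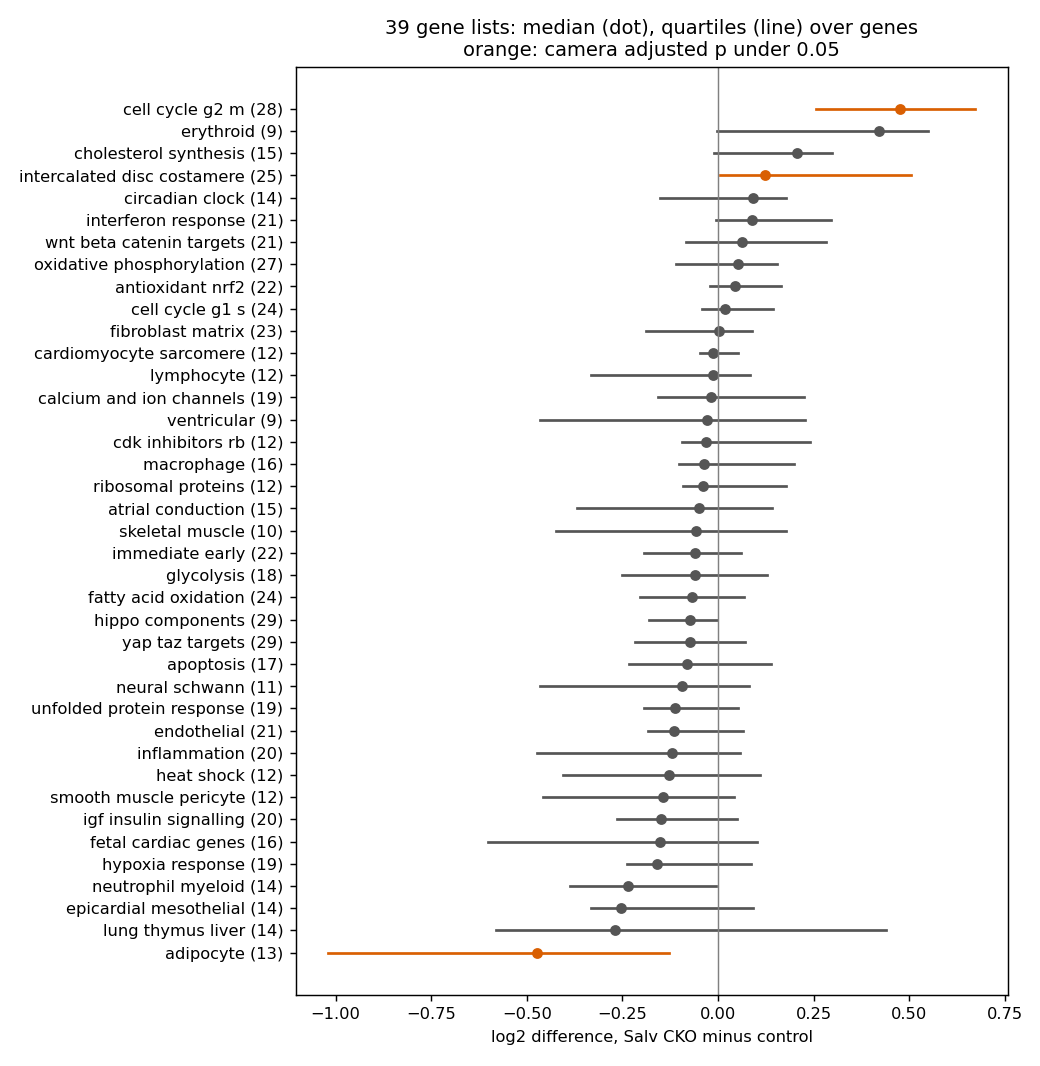
Log2 difference, Salv CKO minus control, of 39 gene lists, with the median as a dot and the quartiles over genes as a line, and the number of measured genes in brackets. The 3 lists with a camera adjusted p under 0.05 are orange, at medians of 0.48, 0.12 and -0.47.

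**Figure D5:**
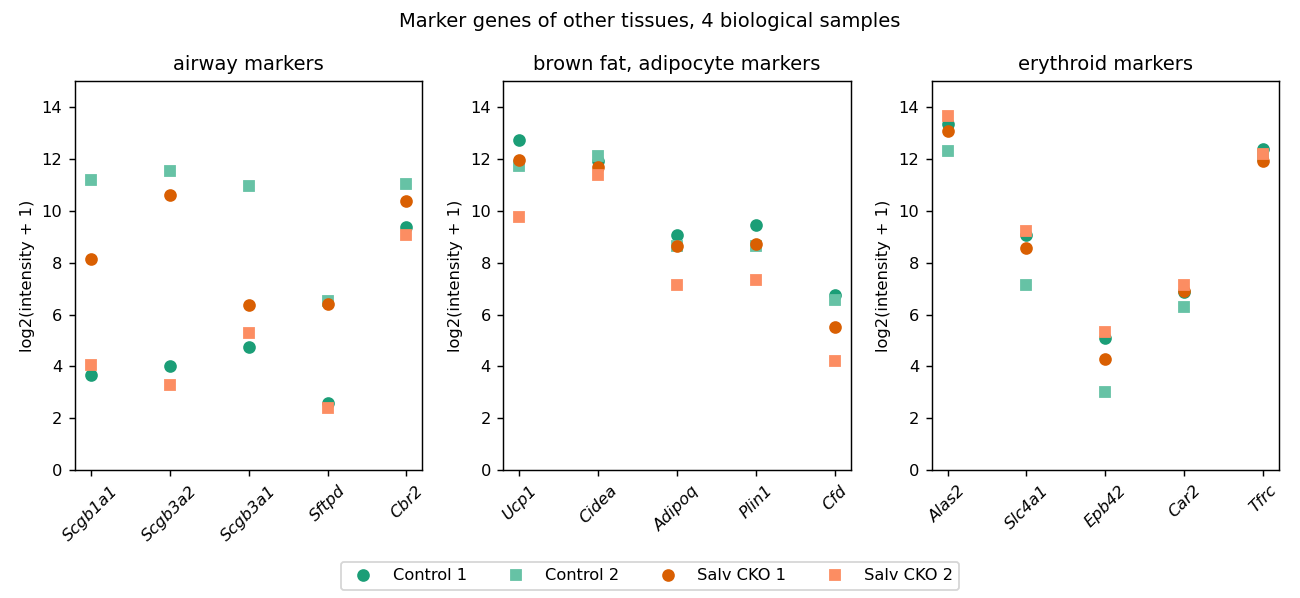
Mean log2(intensity + 1) over 3 technical arrays of markers of airway, brown fat and adipocytes, and erythroid cells in the 4 samples. Ucp1 lies at 9.75 in the sample labelled Salv CKO 2 and from 11.74 to 12.71 in the others.

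The spread between biological samples exceeded that between technical arrays. The median SD over probes was 0.191 between the technical arrays of a sample and 0.270 between the samples of a group. In the brighter 50% of probes these were 0.0893 and 0.198. Across probes, the sample labelled Salv CKO 1 correlated most with Control 2 (r = 0.986) and least with Control 1 (r = 0.976). Genes are not independent replicates, and these correlations describe the samples only.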

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

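No normalization, pseudocount 50, the crossed pairing and the combined setting were chosen after seeing the data. Quantile normalization was chosen once the array distributions were seen to differ, a case for which the design named no method. It is the setting used throughout, for the spread too, and gives no second value. The limma count of 0 of 26423 probes (1048 at unadjusted p under 0.05) stayed at 0 in every setting but 4. It was 61 (34 higher, 27 lower) with the sample as a random block over 12 arrays, 856 (409 higher, 447 lower) with arrays as independent, which counts technical arrays as replicates, 2 (Trim12a and Slx1b) with median centring and 14 (10 higher, 4 lower) without normalization, which shifts the median of all probes by 0.11. The 1048 probes with unadjusted p under 0.05 became 2202 and 5129 in the fits of 12 arrays, and 599 and 327 without the dimmest 25% and 50%, where fewer probes were tested. Sav1 kept its sign in every setting that used all 4 samples. The number of called lists, 3, became 0 with an estimated correlation (adjusted p from 0.516), 5 without normalization and 2 to 7 with samples left out (7 without Control 1). The lone sample is then assumed to vary like the other group.

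The G2 and M list stayed called in all settings except the estimated correlation (0.48, adjusted p = 0.516), from 0.38 to 0.61. The intercalated disc list lost its call with median centring (median -0.066, test still up), no normalization (0.13), no moderation and an estimated correlation (0.12 each), and without Control 1 and without Salv CKO 2, not without the other 2 (0.013 to 0.25 over the 4). The adipocyte list lost it with no moderation, the crossed pairing and an estimated correlation (-0.47 each), and without Salv CKO 2 and without Control 2, not without the other 2 (-0.57 to -0.20 over the 4). Technical SD was 0.191 over all probes and 0.0893 without the dimmer 50%, where the biological SD was 0.198. Causes were not tested.

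The labels share numbers 1 and 2 between groups, but nothing ties same-numbered samples together. Their deviations correlated at -0.25. The replicate block called 0 probes and 3 lists and left Sav1 at -0.12; the crossed pairing called 0 probes and 2 lists.

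Directions turned, by the list test, for results that were not called in either setting (log2 medians of lists and differences of genes, which can keep their sign). With all arrays taken as independent: atrial conduction -0.050. With the replicate block: macrophage -0.037. With the median of technical arrays: Ccn2 0.023. With median centring: G1 and S -0.065, cardiomyocyte sarcomere -0.20, channels -0.19, oxidative phosphorylation -0.16, macrophage -0.15, lymphocyte -0.040. Without the dimmest 25%: channels -0.024, lung, thymus and liver -0.27. Without the dimmer 50% of probes: ribosomal proteins -0.037, neural schwann 0.066. Without moderation: glycolysis -0.060, atrial conduction -0.050. With a pseudocount of 16: atrial conduction -0.049. Without normalization: Lats1 0.032, cardiomyocyte sarcomere -0.0033, oxidative phosphorylation 0.028, macrophage 0.043, lymphocyte 0.15, lung, thymus and liver -0.099. With a pseudocount of 50: lung, thymus and liver -0.085, atrial conduction -0.025. With the crossed pairing: macrophage -0.037, lung, thymus and liver -0.27, circadian clock 0.092. With a pseudocount of 16 and the median of technical arrays: Ccn2 0.023, lung, thymus and liver -0.19. The cause was not tested. With samples left out, ranges that crossed 0 were: Ankrd1 -0.035 to 1.14, Ccn2 -0.47 to 0.39, Lats1 -0.50 to 0.23, Lats2 -0.18 to 0.068, Sav1 -0.46 to 0.21, Stk4 -0.20 to 0.059, antioxidant nrf2 -0.0089 to 0.11, apoptosis -0.24 to 0.080, atrial conduction -0.18 to 0.067, channels -0.032 to 0.042, cardiomyocyte sarcomere -0.021 to 0.019, G1 and S -0.029 to 0.088, circadian clock -0.033 to 0.079, endothelial -0.18 to 0.015, epicardial mesothelial -0.52 to 0.018, erythroid -0.17 to 0.56, fatty acid oxidation -0.10 to 0.017, fibroblast matrix -0.10 to 0.081, glycolysis -0.14 to 0.0038, hippo components -0.19 to 0.057, insulin-like growth factor -0.31 to 0.023, immediate early -0.12 to 0.036, inflammation -0.40 to 0.029, lung, thymus and liver -0.58 to 0.69, lymphocyte -0.27 to 0.16, macrophage -0.095 to 0.10, neural schwann -0.29 to 0.069, ribosomal proteins -0.25 to 0.12, skeletal muscle -0.30 to 0.029, unfolded protein response -0.18 to 0.0038, ventricular -0.28 to 0.080, wnt beta catenin targets -0.039 to 0.15, yap taz targets -0.19 to 0.062. Of these, 4 lists gained a call: without Control 1, lung, thymus and liver (-0.58, adjusted p = 0.0236), erythroid (0.56, 0.00703) and ventricular (-0.28, 0.00951), and without Salv CKO 2, inflammation (-0.40, 0.0233). Outside them, cholesterol synthesis (adjusted p = 0.00703) and smooth muscle (0.0365) were called without Control 1, and smooth muscle (0.0204) without Salv CKO 1. With all samples, cholesterol synthesis was called in 6 settings: both fits of 12 arrays (0.0121 and 0.0119), without the dimmest 25% (0.0497) and 50% (0.0483), and pseudocounts of 16 (0.0243) and 50 (0.0132). Smooth muscle was called in 4: median centring (0.00257), the intensity trend (0.0145), no normalization (0.00289) and the mean over probes (0.0173). The fetal program was called with median centring (0.0111) and no normalization (0.00395), erythroid with no normalization (0.0474), and oxidative phosphorylation without moderation (0.000257). Of 36 lists without a call, 8 were called in 21 of 720 list settings.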

Other observations

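The tests of a mislabelled sample, of blood cell precursors and of alveolar tissue were chosen only after their results were seen, as was the count for single samples with the median of technical arrays.

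Several genes of other tissues differed between samples without following the groups. Scgb3a2, a secretoglobin of airway epithelium, stood at log2 levels of 10.61 in Salv CKO 1 and 11.55 in Control 2, against 3.29 in Salv CKO 2 and 4.02 in Control 1. The surfactant protein gene Sftpd stood at 6.39 and 6.54 against 2.39 and 2.60. Lung or airway tissue left on the dissected hearts is a candidate source. Of 14 further airway markers, 7, or 50%, were higher in both of these samples than in both others. Chance gives 16.7% if all orders of the 4 samples are equally likely, and the share over all genes was not counted. Of 101 brighter genes differing by more than 1 between these samples and the others, each side within 0.5, 87 were higher in these. Among the 7 airway markers, Scgb3a1 differed by 3.65, with 6.37 and 10.96 against 5.27 and 4.76. Tff2, Sec14l3 and Cbr2 differed by 2.27, 2.06 and 1.46. The difference in Tff2 came mostly from Control 2, at 7.29, with Salv CKO 1 at 3.86 against 3.36 and 3.25. Bpifa1, also among the 7 markers, was dim, at levels of at most 3.42. Tppp3 was not among them (11.60 and 12.21 against 11.61 and 11.54), and Foxj1, of ciliated cells, went the other way (at most 7.24 against at least 8.53, a difference of -2.16). Of 12 alveolar markers, 6, or 50%, were higher in both of these samples. Sftpc stood at 5.19 and 5.62 against 4.59 and 4.67, and Slc34a2, at levels of at most 1.52, was near background. The airway list met the bound set beforehand for such tissue (50%, median difference 0.37). The alveolar list met the same bound (50%, median difference 0.41), applied after its result was seen. The values do not all point one way, and such tissue stays open.

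The sample labelled Control 1 stood apart from the other 3. With a difference of at least 1 and the others within 0.5, it differed for 237 genes, 188 lower and 49 higher, where the other samples each differed for 15 to 23. With the median of technical arrays, which a single failed spot does not move, the counts were 228 and 7 to 19, and 194 genes were in both Control 1 sets. It had the lowest mean correlation with the others (r = 0.979).

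Sav1 was lower in the samples labelled Salv CKO 1 and Control 2 than in the others, against the labels, by 0.57, a size at the 84.4 percentile of all genes and the 87 percentile of genes of similar level, so ordinary spread between samples stays open. The samples labelled Salv CKO 1 and Control 2 were also the dimmest, with mean intensities of 623 and 681. Control 1 had 770 and Salv CKO 2 had 840. For the brighter 50% of probes, the tables argue against brightness that varies between technical arrays of a sample as the source. Across these probes, its highest correlation with this difference within a sample was 0.0394, where 0.54 or more would be expected. Dimmer probes were left out of this test. A cause of dimness shared by all arrays of a sample could not be tested this way and stays open. A block of changed genes around Sav1 stays open: in this split, its 20 nearest measured genes lay at the 80.6 percentile of random windows. Under the bound set beforehand, below the 95th percentile, this value counted against a block. That bound was wrong by design, a reading made after the value was seen. The window is judged by its median, which rises only if most of its genes differ. A block need not change most of the genes in it, so the window cannot decide. A block that follows the labels was not tested, because the window was not compared in the labelled split. An exchange of the labels of Salv CKO 2 and Control 2 stays open: the median of the G2 and M genes in the split it implies was -0.056, against 0.48 as labelled. A probe outside the deleted part also stays open, untested.

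That split, of Salv CKO 1 and Control 2 against the other 2 samples, gave 2235 probes at an unadjusted p under 0.05, against 1048 as labelled and 638 to 2824 as labelled with 1 sample left out. It called 0, 107 and 12 probes at pseudocounts of 1, 16 and 50, against 0 each as labelled. At the latter settings this points to a structure of the samples other than the labels. The list of lung, thymus and liver markers parted the samples in the same way, with 14 of 14 genes positive, a median of 0.67 and a camera adjusted p of 7.54e-07 at the preset correlation. It includes Scgb3a2 and Sftpd, whose levels above already part the samples this way, so the list test partly restates them. With an estimated correlation 0 lists were called in that split, as in the labelled split and the split by number. The lung, thymus and liver markers, higher in Salv CKO 1 and Control 2, parted the samples as the lower Sav1 and the additional probes did. The source of these markers stays open. The split also parts the dimmer from the brighter samples, so a technical source cannot be told apart. What share of the probes goes with the markers was not tested.

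The G2 and M genes were higher in both samples labelled Salv CKO. The tables argue against normalization as the source: the lower of the medians without it and with median centring was 0.42. The 4 samples allow 3 splits, too few for a share under 0.05, and 1 split, the labelled one, gave a median as large. Its value was 0.48, and the highest of the others was 0.056 in size. Blood cell precursors may contribute and cannot be told apart from heart cells: the erythroid median of the lower Salv CKO sample minus the higher control was -0.18, with 9 markers measured. The effect of the mutation named by the design stays open, untested beyond these samples.

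Strain haplotypes of the hybrid background may underlie large differences of single genes. The 428 genes with such differences formed 40 neighbouring pairs against 30.9 in random sets (permutation p = 0.0521), which leaves this open. These genes were taken from means of technical arrays and include Ubn2 and Cst11, whose differences rested on 1 array of each sample of 1 group. A pair had to lie within 3 measured genes, with symbols that start differently, so the count could not see wider blocks. Of the 7 sets behind this count, that of Control 1 alone formed 16 pairs against 9.60 (permutation p = 0.0302, or 0.211 adjusted over the 7 sets), and that of the exchanged split 1 against 1.75.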
